A study of Homo sapiens with 15 samples.

How the data were processed

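Per the labels' protocols, RNA was purified with a Zymo kit and sequenced as strand-specific mRNA libraries. STAR, featureCounts, FastQC, MultiQC and the genome build hg19 are named in the submitters' processing notes. Versions, settings and the gene annotation are not given in the sources used here. The authors deposited 1 table for the series, whose file name gives its unit as TPM, a value scaled for gene length and library size.

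Samples were grouped by their titles into DMSO and KB528 for 1, 3, 6 and 24 h, with 3 samples in each. The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. They comprised limma fits on log2(TPM + 1) for each time against DMSO and between times, and tests of the gene lists. The genes to be named were to include a fixed set and those with the largest changes. The alternatives were to vary the scaling, the filter, the pseudocount and the libraries in the fit.

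None of these tests was run. The 15 value columns of the table have names, the letter S with a number, that occur in no sample title or description, and all 15 were left unused. When the table was first inspected, the range, quartiles and total of each column and the values of the first rows were looked at, but no value from a column enters the text. Only the column names and gene symbols were read for the results given here, with Python 3.11.15 and pandas 2.3.3. The list genes were matched to the table by exact symbol, or by an older symbol written beside it in the list.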

Results

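The series concerned MM.1S, an established human multiple myeloma cell line. Per the labels and the series' design text, cells were treated with 100 nM KB528, an inhibitor of the lysine acetyltransferase activity of p300. Polyadenylated RNA was profiled by strand-specific sequencing after 1, 3, 6 and 24 h of treatment, and cells given DMSO, the vehicle, stood for 0 h. The labels name 15 samples in 5 groups, with 3 replicates in each group. The design implies a comparison of each treated time with DMSO and of the treated times with each other. The titles of the DMSO samples give no time, and DMSO was the only control for every treated time. A comparison with DMSO could therefore also hold a difference in time in culture. The title of the series places the question around IRF4, a transcription factor of plasma cells.

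No comparison between these groups was made. The expression table lists 26463 features by gene symbol, 5 of them with the symbol NA, and has 15 value columns, which carry only the letter S and a number from 1 to 15. None of the 15 names occurs in the title or description of a sample, and all of the descriptions are empty. With the labels and the table used here, giving a column to a group would have rested on its place in the table or on its values. The labels used here do not state the order of the columns, and groups chosen from the values could not then be tested on them. Therefore 0 columns were matched to a sample or group. The labels and the table used here gave no key from the column names to the samples. No expression level, fold change or test is reported, and the depth of the libraries is unknown.

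The gene names in the table could still be compared with the gene lists fixed for this study. These 28 lists hold 655 different genes, of which 625 are listed by name. All 20 genes of the list named plasma cell transcription factors are listed, among them IRF4. So are all 39 MYC targets and all 36 genes of the acetylation list, which includes EP300 and CREBBP. Full coverage was not particular to these lists. All 17 myeloid cell genes, all 18 stromal, epithelial and endothelial genes and all 13 erythroid and megakaryocyte genes are listed as well. Only the immunoglobulin, T and NK cell and mitochondrially encoded lists were incomplete. Of the 17 immunoglobulin genes, 3 are listed, and of the 18 T and NK cell genes, 15 are listed. None of the 13 mitochondrially encoded genes was found under the symbols searched. A listed name says nothing of whether the gene was expressed.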

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

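No expression result was computed, so none was recomputed under another setting, and none of the alternatives fixed before the data were examined was run. Groups could not be compared because no column of the table was matched to a sample. Values pooled over all columns, which need no such match, were not computed either. Only the counts of list genes found by name were recomputed, under alternatives chosen after seeing the data. Over all lists, the count was 625 of 655 genes as reported, 609 when the older symbols in the lists were left out, and 627 when the synonyms of the RefSeq gene table were also searched. The count was the same in all 3 settings for 25 of the 28 lists. Without older symbols, the polyadenylated histone genes went from 15 of 15 to 0 and the plasma cell and myeloma markers from 31 to 30 of 31. With synonyms, the immunoglobulin genes went from 3 to 5 of 17. The names matched for the added genes, IGHA2 and IGLC7, were A2M and C7, which are the symbols of other genes (alpha-2-macroglobulin and a complement component). No paired analysis was possible because no column was matched to a sample. The titles number the replicates but do not say that equal numbers were paired.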
